A study of Populus davidiana with 6 samples.

How the data were processed

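Leaf RNA from plants of Populus davidiana cultivar Palgong2 was sequenced from 3 control and 3 air-dried samples. Per the labels' protocols, poly(A) RNA from 2 µg of total RNA with an RNA integrity number of at least 7 was used for TruSeq libraries, which were read as 100 bp paired ends on a HiSeq instrument. Whether the library kit kept strand is not given in the sources used here, so reads of overlapping loci on opposite strands cannot be assigned with certainty. Of the 496 loci with 2-fold rises 39, and of the 67 with 2-fold falls 10, overlap a tested locus whose strand label differs, unassigned strand included. Overlaps with untested loci were not counted. Per the submitters' processing notes, the tools were FastQC, TopHat and Cufflinks, without versions. The genome build and the annotation are not given in the sources used here.

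The deposited files list, per the file headers, FPKM for each of 112919 transcripts in each sample, with a locus identifier, position, strand and a status of known or new. The authors' FPKM divide fragments by transcript length and library size, so the fragments behind a value are not visible. Very short transcripts can reach very high FPKM: those spanning under 500 bases held between 29.8% and 94.3% of the summed FPKM of a library, and that sum ranged from 1264230 to 21126700, so it says little of depth. Absolute depth is unknown, and relative depth was estimated from low values (under 0.08 FPKM, at loci of 1 transcript spanning over 1500 bases), as a multiple of control replicate 1.

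FPKM of all transcripts of a locus were summed. Loci with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 22729 and dropped 17808. On log2(FPKM + 1), air-dried and control libraries were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, no covariates), with Benjamini-Hochberg adjustment at 0.05. The groups, the test, most alternatives and the rule for named genes were fixed before the data were examined. The rule for named genes asked for named or described genes and members of 26 gene lists, and allowed 2 identifiers with the largest rise and 2 with the largest fall where no names were at hand. Since the files pair no identifier with a name or description, the last part applied. The 26 lists, the gene set test and the genes for 9-cis-epoxycarotenoid dioxygenase were not analysed here. Loci given only by position were chosen afterwards, as stated where they appear.

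On simulated data, with 50 loci changed per size and direction among 22729 loci in the comparison of air-dried with control libraries, limma called 70% of loci with a log2 change of 1, 66% of those at -1, 94% at 2 and 84% at -2, and 4 of 161 calls were false. The simulated noise was normal, independent and of equal size in every library. The real libraries were unequal, with estimated weights of 0.290 for air-dried replicate 1 and 7.50 for air-dried replicate 3, so these shares may not carry over. Adjacent pairs were counted among tested loci on numbered chromosomes and compared with 10000 shuffles of the calls within chromosome and class of span. The check with simulated calls on 22030 loci used fewer shuffles, within chromosome alone and not within class of span. Its permutation p was 0.471 for random calls and 0.002 for calls with 15 planted pairs, the smallest those shuffles can give. The shuffle within class of span was not checked this way. Spans are genomic and include introns.

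Alternatives fixed in advance were the pseudocount (0.1 and 5), the filter on low values (none, or 5 FPKM), median-of-ratios, quantile and upper-quartile scaling, the replicate number as a block, library weights, no mean-variance trend, each library left out in turn, and transcripts in place of loci. Annotated parent genes in place of loci, and only loci with no transcript spanning under 500 bases, were added after the data were seen. Filtering on the quantification status was not run, since the files carry no such status. Figures were drawn with matplotlib 3.10.9.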

Results

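Leaf transcriptomes of the Korean aspen Populus davidiana, cultivar Palgong2, which the labels call drought tolerant, were measured by poly(A) RNA sequencing in 3 control and 3 air-dried libraries. The plants had been grown in vitro on sugar-containing medium for about 6 weeks. Treated plants were lifted from the medium, rinsed with sterile water and exposed to open air for about 10 min. Whether control plants were also lifted and rinsed is not given in the sources used here, so the values compare the whole handling and drying procedure with the control state. The labels call the leaf samples triplicates without saying that each came from a separate plant or culture, so p-values measure only the spread between these samples, which may be technical. Drought-sensitive plants, which the growth description also mentions, were not analysed here.

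The files held 112919 transcripts, 45773 of them annotated and 67146 assembled from the reads, which were summed into 40537 loci. Between 22227 and 22702 loci reached 1 FPKM (fragments per kilobase of transcript and per sequencing depth of the library) in each library. Absolute depth is unknown, because the files hold no counts. Relative depth was read from the smallest values of low loci, which step with single fragments, by a search up to 3 log2 units to each side of equal steps. It came to 0.954 and 1.01 times that of control replicate 1 in control replicates 2 and 3, and to 0.991, 0.909 and 1.01 times in air-dried replicates 1, 2 and 3. The densest step held 75 to 113 of the 129 to 157 loci compared per library, within 0.1 log2 units, against 14 to 16 at the next densest.

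Control libraries correlated with each other more closely than with any air-dried library, while air-dried replicate 1 was no closer to air-dried replicate 2 than some control libraries were to air-dried replicate 3. Across the 21166 tested loci with no transcript spanning under 500 bases, Pearson correlations of log2(FPKM + 1) were 0.977 to 0.984 among controls, 0.961 to 0.987 among air-dried libraries and 0.937 to 0.963 between groups. These are correlations across loci, which are not independent replicates. With all 22729 tested loci the values were 0.950 to 0.958, 0.893 to 0.966 and 0.878 to 0.938. Air-dried replicate 1 stood apart at short loci: it exceeded the mean of air-dried replicates 2 and 3 by a median of 2.85 log2 units at loci spanning up to 300 bases and by 0.78 at loci of over 300 and up to 500 bases, against 0.04 to 0.13 at longer ones. Principal components were taken on the 21166 tested loci with no transcript spanning under 500 bases. The first, with 49.8% of the variance, separated control from air-dried libraries. The second, with 25.7%, separated air-dried replicate 1 from the other air-dried libraries, so that library also stood apart without the short loci.

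The comparison of air-dried with control leaves asks which transcripts change within minutes of drying in this cultivar. Large changes were mostly increases. Of 22729 tested loci, 496 rose at least 2-fold and 67 fell at least 2-fold, so that 88.1% of the 2-fold changes were rises. The loci with 2-fold rises went from a median of 4.03 FPKM in control leaves to 17.3 FPKM in air-dried leaves, and those with 2-fold falls went from 13.0 to 3.73 FPKM. At 4-fold or more the numbers were 152 and 6, and at 8-fold or more they were 57 and 3. A set of 24 loci lay below 1 FPKM in every control library and at 5 FPKM or more in every air-dried library, and 3 loci showed the opposite.

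Without a size limit, 1655 loci were higher and 638 lower in air-dried leaves (limma with a mean-variance trend on log2(FPKM + 1), two-sided, adjusted p under 0.05 by Benjamini-Hochberg), which is 10.1% of those tested. All 496 and all 67 loci changed at least 2-fold had air-dried values entirely outside the control range. A 2-fold call with 3 libraries per group favours such loci, so this is not separate evidence. The groups did not overlap at 7477 tested loci, or 32.9%, where chance gives 10% for 3 against 3 libraries. Fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed loci. The excess of rises among all calls depended on scaling: rises made up 72.2% of calls in the deposited values, 56.1% (1315 higher, 1031 lower) after median-of-ratios scaling, 45.5% (996 and 1191) after quantile normalization and 45.9% (1111 and 1308) after upper-quartile scaling, as the median change of all tested loci moved from 0.07 to 0.00, -0.05 and -0.05, whereas 2-fold changes stayed 83.2%, 77.7% and 79.1% rises. The 2-fold counts moved with the pseudocount, to 265 rises and 25 falls at 5 and to 110 falls at 0.1, library weights gave 146 falls and 4326 higher and 2108 lower loci, and testing transcripts in place of loci gave 606 higher and 131 lower. Leaving out any 1 of control replicates 1, 2 and 3 or air-dried replicates 2 and 3 brought the calls to 877, 987, 876, 1018 and 795 higher and 238, 317, 231, 300 and 237 lower, and leaving out air-dried replicate 1 raised the 2-fold falls to 129, while quantile and upper-quartile scaling gave 118 and 111.

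**Figure D1:**
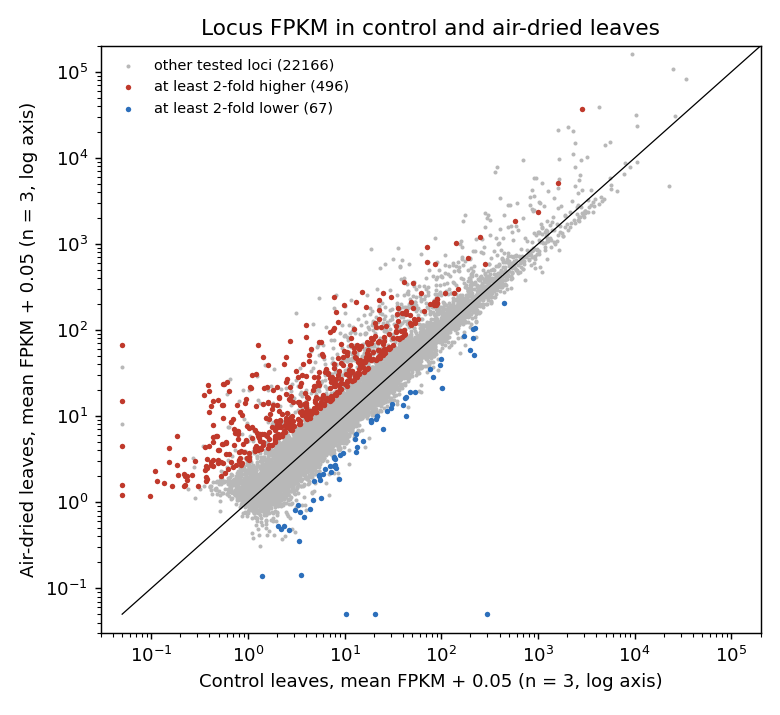
Mean FPKM per tested locus in 3 control libraries (horizontal) and 3 air-dried libraries (vertical), both on log axes after adding 0.05, with loci changed at least 2-fold in red (rises) or blue (falls), a diagonal for equal means and 1 tested locus outside the drawn range. The 496 rises lie above the diagonal and outnumber the 67 falls below it.

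The 12 largest rises on the log2(FPKM + 1) scale among loci that met the criteria given here started from control means of 0.339 to 14.96 FPKM, and ratios from the lowest of these are imprecise. The files pair no locus with a gene name, and no genome or annotation was used here, so loci are given by position, on a build that is not given in the sources used here. The following loci were chosen after their values were seen, as those with the largest log2 changes on that scale among annotated single-gene loci with all transcripts spanning at least 500 bases, no overlapping tested locus and FPKM above 0 in every library. Only called loci whose air-dried values all lie outside the control range were eligible, so neither property is a result here. On chromosome 5 at 24433589 to 24435408, FPKM rose from 2.66 ± 0.255 to 74.7 ± 2.78 (mean ± SD, n = 3 per group throughout), a log2 change of 4.37 with a standard error of 0.08. A locus on chromosome 2 at 997286 to 1003043 rose from 1.38 ± 0.319 to 48.9 ± 1.85. On chromosome 9, the locus at 12284978 to 12286144 rose from 8.03 ± 1.04 to 162 ± 8.45, and the locus at 9000204 to 9001004 from 0.520 ± 0.128 to 23.6 ± 0.577. A locus on chromosome 4 at 20365509 to 20366795 rose from 9.77 ± 0.221 to 194 ± 21.8, and a locus on chromosome 14 at 1643749 to 1644810 from 14.96 ± 1.46 to 280 ± 7.93. On chromosome 15, FPKM rose from 0.503 ± 0.0738 to 23.3 ± 4.07 at 9842656 to 9845099 and from 1.57 ± 0.0648 to 39.4 ± 8.54 at 11334262 to 11335715. On chromosome 18, it rose from 1.04 ± 0.108 to 30.3 ± 2.85 at 8591115 to 8592969 and from 1.21 ± 0.347 to 67.2 ± 33.5 at 9245946 to 9246542. On chromosome 6, it rose from 0.345 ± 0.139 to 19.5 ± 2.22 at 22192804 to 22193878. The adjusted p of these rises lay between 2.687e-05 and 0.000684.

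Other loci that rose were already abundant in control leaves. The locus on scaffold_393 at 11083 to 13025 rose 7.36-fold, from 141 ± 5.60 to 1035 ± 42.0 FPKM (n = 3 per group). A locus on chromosome 3 at 14941797 to 14943066 rose 8.78-fold, from 41.1 ± 1.21 to 360 ± 44.5 FPKM. Rises of about 2-fold were seen on chromosome 6 at 6385061 to 6388308, from 280 ± 15.4 to 582 ± 24.9 FPKM, and on chromosome 4 at 1305838 to 1307624, from 149 ± 18.8 to 299.7 ± 14.9 FPKM. The calls of these 2 loci were lost after quantile normalization (limma, adjusted p = 0.125 and 0.0767). All 4 loci were selected after the values were seen, as those with the highest level in air-dried leaves among loci with 2-fold rises, an annotated transcript of a single gene, all transcripts spanning at least 500 bases and no overlapping tested locus, criteria that left out some loci with higher levels.

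The 2-fold falls had a median log2 change of -1.23. Among loci chosen by the same criteria, the locus on chromosome 4 at 17844923 to 17845770 fell from 101 ± 29.9 to 21.1 ± 4.26 FPKM (n = 3 per group), a log2 change of -2.17 with a standard error of 0.26. On chromosome 2, FPKM fell from 220 ± 45.1 to 51.7 ± 7.64 at 22447102 to 22447777 and from 3.34 ± 0.617 to 0.301 ± 0.125 at 4117184 to 4118817. A locus on chromosome 19 at 15328870 to 15331637 fell from 42.9 ± 4.55 to 9.95 ± 1.17. On chromosome 5, FPKM fell from 8.62 ± 0.560 to 1.79 ± 0.178 at 21253478 to 21255127 and from 13.4 ± 0.406 to 4.31 ± 0.855 at 4002022 to 4006779. A locus on chromosome 13 at 15131922 to 15133908 fell from 211 ± 29.5 to 80.5 ± 13.3, and a locus on chromosome 15 at 13842976 to 13845490 from 3.76 ± 0.305 to 0.629 ± 0.135. Further falls were seen on chromosome 6 at 18074879 to 18081844, from 15.4 ± 0.446 to 5.04 ± 0.542, and on chromosome 9 at 1242309 to 1246446, from 13.2 ± 0.349 to 3.82 ± 0.535. All 12 falls chosen this way had adjusted p between 0.00026 and 0.01004.

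The largest estimated changes, chosen by the rule fixed before the data were examined, were at loci that were mostly very short. Only called loci whose air-dried values all lie outside the control range were eligible. POPTR_0018s05900, an annotated locus of 316 bases on chromosome 18 at 5529609 to 5529924, stood at 5.24, 18.0 and 0 FPKM in the control libraries and at 260, 266 and 200 FPKM in the air-dried libraries (log2 change 5.62 with a standard error of 1.02, adjusted p = 0.0237). XLOC_029909, an assembled locus of 156 bases on chromosome 5 at 20597975 to 20598130, was listed at 0 in every control library and at 147, 41.2 and 12.3 FPKM in air-dried replicates 1, 2 and 3 (adjusted p = 0.0126), and lies in the span class in which air-dried replicate 1 stood furthest from the other air-dried libraries. XLOC_040215, an assembled locus of 114 bases on scaffold_705 at 6391 to 6504, was at 357, 323 and 205 FPKM in control libraries and was listed at 0 in every air-dried library (adjusted p = 2.772e-05). POPTR_0008s03650.r1, a single assembled transcript on chromosome 8 at 1982262 to 1997713 that overlaps another locus, was at 11.9, 26.5 and 22.7 FPKM in control libraries and was listed at 0 in every air-dried library (adjusted p = 0.000602). The call of POPTR_0018s05900 was lost without control replicate 1 or air-dried replicate 1, 2 or 3 (adjusted p = 0.0809, 0.0507, 0.0793 and 0.0799) and with a pseudocount of 0.1 (0.0772), and that of XLOC_029909 without control replicate 1, 2 or 3 or air-dried replicate 2 (0.0568, 0.0527, 0.0563 and 0.0509). Counted under its annotated parent gene, a unit chosen after the data were seen, POPTR_0008s03650.r1 had a log2 change of -0.87 (adjusted p = 0.0585).

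**Figure D2:**
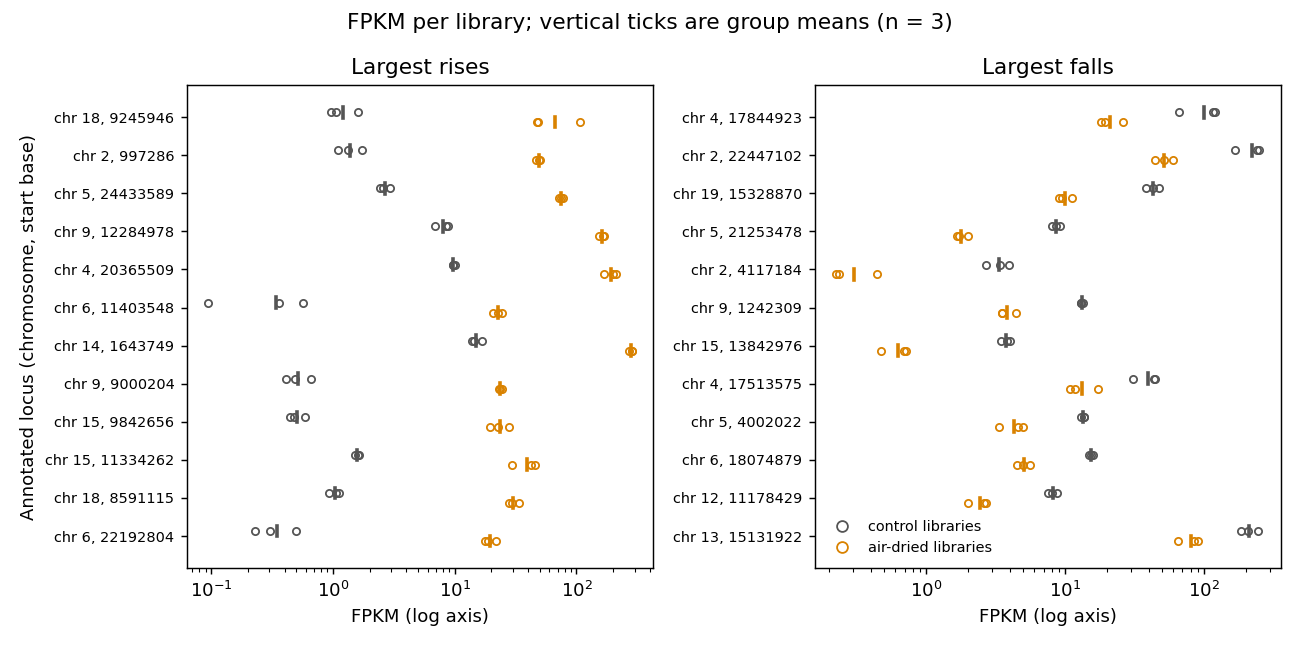
FPKM (horizontal, log axis) of the 12 rises and 12 falls given by position, labelled by chromosome and start base, with a circle for each of 3 control and 3 air-dried libraries and a vertical tick for each group mean. By selection, the air-dried libraries lie entirely on one side of the control libraries at each of these loci, as on chromosome 5 at 24433589, where FPKM rose from 2.66 to 74.7.

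The 2-fold rises were concentrated in loci spanning over 500 and up to 2000 bases and in loci with 1 transcript. Of loci whose genomic span was over 1000 and up to 2000 bases, 6.46% rose at least 2-fold (208 of 3219, 95% Clopper-Pearson interval 5.64% to 7.37%), against 0.597% of loci over 4000 and up to 8000 bases (41 of 6871, 0.429% to 0.809%), an odds ratio of 11.5 (8.17 to 16.5, Fisher's exact test, two-sided, p = 3.297e-65). The share was 6.52% over 500 and up to 1000 bases, 1.51% above 2000 and up to 4000 bases and 0.925% above 8000 bases, and was lower again over 300 and up to 500 bases (2.71%) and up to 300 bases (1.43%). At these shortest loci air-dried replicate 1 stood apart from the other air-dried libraries, which makes calls harder to reach. The share of falls was 1.04% over 300 and up to 500 bases (5 of 480, 0.339% to 2.41%) and 0.890% over 500 and up to 1000 bases (12 of 1349, 0.460% to 1.55%). These intervals overlap, so the 2 classes cannot be ranked. Falls made up 0.559% over 1000 and up to 2000 bases, 0.131% above 4000 and up to 8000 bases and 0.0711% above 8000 bases. Loci with 1 transcript rose at least 2-fold in 5.12% of 6033 cases and loci with more in 1.12% of 16696 (odds ratio 4.77, 3.95 to 5.76, Fisher's exact test, two-sided, p = 5.970e-64). Of loci with annotated transcripts only, 294 of 5196 (5.66%) rose at least 2-fold. The share was 150 of 14252 (1.05%) at loci of an annotated gene that held assembled transcripts, including loci such as POPTR_0008s03650.r1 with no annotated transcript. It was 19 of 1080 (1.76%) at loci tied to no annotated gene, and 33 of 2201 rose where several annotated genes were merged. These intervals treat loci as independent and cover counting error only. Span, transcript number and class are not separate traits. Span classes up to 2000 bases held a median of 1 transcript per locus, and longer classes medians of 3 to 7. The median span was 1678 bases at loci with annotated transcripts only and 4042.5 bases at loci of an annotated gene that held assembled transcripts. Whether transcript number or class matters at equal span was not tested.

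**Figure D3:**
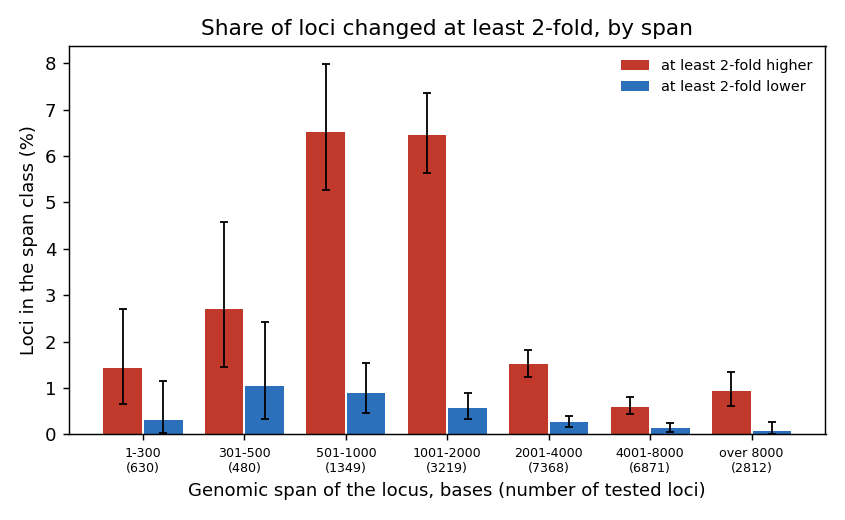
Percent of tested loci changed at least 2-fold, by class of genomic span in bases, for rises and falls, with 95% Clopper-Pearson intervals as bars. Rises reach 6.52% and 6.46% in the classes up to 1000 and up to 2000 bases and stay below 3% in the other classes.

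Loci that rose lay next to each other along the chromosomes more often than shuffled positions did. Of 22030 tested loci on numbered chromosomes, 32 adjacent pairs both rose at least 2-fold, against a mean of 11.1 pairs and a highest value of 26 in 10000 shuffles within chromosome and span class (one-sided permutation p = 0.0001, the smallest these shuffles can give). Of the 32 pairs, 10 overlapped, where reads cannot be assigned with certainty, and the other 22 compare with a mean of 10.6 and a highest value of 26 (p = 0.0018, permutation, one-sided). Among pairs more than 5000 bases apart there were 16, against 6.15 (p = 0.0006, permutation, one-sided). With a pseudocount of 5 in place of 1 the number of pairs was 13, among 265 loci with 2-fold rises in place of 496. No shuffles were run at that setting, so 13 cannot be set against the mean of 11.1. The longest run held 4 adjacent tested loci on the plus strand of chromosome 6, between 11398834 and 11450511, with 2 untested loci between them. Their FPKM rose from 0.298 ± 0.171 to 17.3 ± 2.15, from 0.339 ± 0.235 to 22.6 ± 1.93, from 0.914 ± 0.370 to 15.8 ± 1.04 and from 12.8 ± 2.12 to 48.3 ± 6.21 (n = 3 per group), and the next tested locus, at 11454081 to 11458844 on the minus strand, went from 36.1 ± 3.08 to 52.8 ± 2.98, a rise below 2-fold (adjusted p = 0.0152). That last call was lost without control replicate 1 or 3 or air-dried replicate 3 (limma, adjusted p = 0.0712, 0.0668 and 0.0608) and after quantile normalization (0.0523). The run was picked out after its values were seen.

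**Figure D4:**
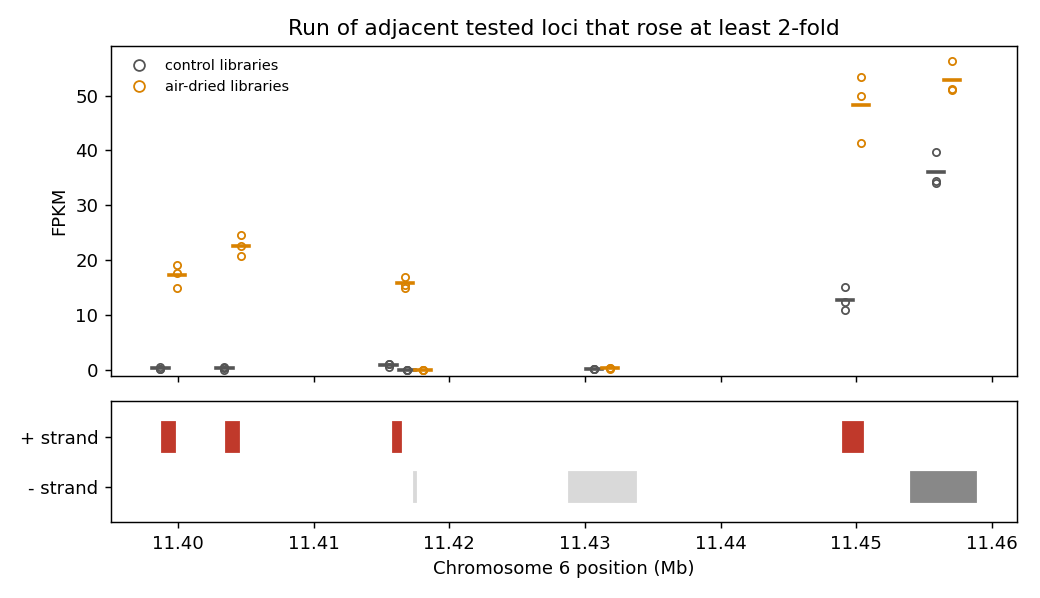
FPKM of loci in a stretch of chromosome 6 by position in Mb, with control and air-dried libraries drawn as circles set slightly to each side of the locus midpoint, short lines for group means, and boxes by strand for loci that are red where changed at least 2-fold, dark grey where tested without reaching 2-fold and light grey where not tested. The 4 loci between 11398834 and 11450511 reach 15.8 to 48.3 FPKM in air-dried leaves from 0.298 to 12.8 FPKM in controls.

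No numbered chromosome held a share of 2-fold rises or falls that differed from all other tested loci, those on scaffolds included, after adjustment over 38 tests. The lowest adjusted p was 0.0644 for both chromosome 6, where 57 of 1744 tested loci rose (3.27% against 2.09% elsewhere), and chromosome 4, where 10 of 1246 fell (0.803% against 0.265%, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). Within loci, transcripts changed unequally at 129 of 10643 loci with at least 2 tested transcripts (limma diffSplice with Simes adjustment, Benjamini-Hochberg 0.05), and at 106 of these the locus total was not called. Annotated transcripts rose at least 2-fold in 325 of 18729 tested cases (1.74%) and assembled transcripts in 101 of 22197 (0.455%).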

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

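Annotated parent genes and the restriction to loci with no transcript spanning under 500 bases were tests chosen after the results were seen. All 563 loci with 2-fold changes kept their direction under every planned locus-level setting that still tested them, and between 487 (without air-dried replicate 3) and 562 stayed called over the 15 settings that tested all of them, with 495 under the replicate block, 493 to 498 without a control replicate, 497 and 539 without air-dried replicates 2 and 1, and 549 after quantile normalization. The air-dried values of these loci all lay outside the control range, so among these settings only the scalings could have reversed a direction. With a pseudocount of 0.1 the 2-fold falls numbered 110, and with a pseudocount of 5 the 2-fold rises and falls numbered 265 and 25, since a larger constant shrinks log2 changes. Median-of-ratios scaling gave 1031 lower loci. Quantile normalization gave 996 higher, 1191 lower and 118 2-fold falls, and upper-quartile scaling 1308 lower and 111 2-fold falls, as both shift the median change below 0. Library weights gave 4326 higher, 2108 lower and 146 2-fold falls, with a weight of 7.50 for air-dried replicate 3 and 0.290 for air-dried replicate 1. Testing transcripts gave 606 higher and 131 lower, the cause of which was not tested. Leaving out 1 library gave 795 to 1449 higher, 231 to 688 lower, 455 to 512 2-fold rises and 53 to 129 2-fold falls, with fewer samples in each fit. The replicate block gave 753 higher and 175 lower loci, and the cause was not tested. The numbers were not taken to pair the samples: same-numbered libraries had deviations correlated at 0.06, 0.22 and -0.19, and not every sample correlated best with its own number. With 3 libraries per group, these correlations cannot exclude pairing. Parent genes gave 1591 higher and 609 lower, and loci without short transcripts 2022 and 821. The odds ratio for spans ranged from 7.57 to 21.7 over 17 settings, and adjacent pairs from 13 to 40, with no shuffles run per setting. Of 430 values for the 12 largest rises and 12 largest falls given by position, 0 lost the call (limma; highest adjusted p 0.0497). Of 334 values for 19 other loci given by position 20 lost it, at 7 loci, and of 69 for the 4 identifiers 10 did. None of these reversed, which only a scaling or the parent-gene unit could have brought about, since the groups did not overlap at these loci. With the replicate block, the chromosome 10 locus at 17667838 and the chromosome 6 locus at 11454081 lost the call (adjusted p = 0.0547 and 0.0732), and with no filter the chromosome 2 locus at 22451210 did (0.0600), where alternatives for these 19 loci ranged from 1.418e-06 to 0.138. DESeq2 and edgeR alternatives were not run because the files hold no counts, nor were the gene set tests and the status filter. Without counts, precision at low FPKM cannot be set from depth.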

Other observations

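The tests of scaling and of air-dried replicate 1 as causes of the excess of rises, of the adjacency of falling loci and of the strand of rising pairs were chosen after the result was seen. Falling loci also lay side by side. Of the loci with 2-fold falls, 4 adjacent pairs were found against a mean of 0.197 in 10000 shuffles (one-sided permutation p = 0.0001, the smallest these shuffles can give). Without the pair that overlaps there were 3 against 0.187 (permutation p = 0.001, one-sided), and 1 pair was more than 5000 bases apart, against 0.107 (permutation p = 0.10). On chromosome 2 at 22447102 to 22452035, neighbours on the same strand fell from 220 ± 45.1 to 51.7 ± 7.64 FPKM and from 197 ± 95.6 to 58.6 ± 19.6 FPKM (n = 3 per group). On chromosome 9 at 11230126 to 11233124, neighbours fell from 30.2 ± 4.63 to 12.5 ± 0.500 FPKM and from 24.9 ± 2.79 to 6.97 ± 1.27 FPKM. On chromosome 10 at 10174201 to 10183853, they fell from 4.79 ± 0.669 to 1.70 ± 0.390 FPKM and from 6.26 ± 0.855 to 2.41 ± 0.748 FPKM. The remaining pair, on chromosome 4 at 17538339 to 17547186, overlaps. Some of these calls were lost when 1 library was left out (limma, adjusted p in parentheses). The chromosome 2 locus at 22451210 lost its call without control replicate 1, 2 or 3 or air-dried replicate 2 or 3 (0.0775, 0.0825, 0.0848, 0.122 and 0.138). The chromosome 10 locus at 10182603 lost it without control replicate 1, 2 or 3 (0.0613, 0.0593 and 0.0729), and the chromosome 4 locus at 17538339 without control replicate 3 or air-dried replicate 2 or 3 (0.0722, 0.0512 and 0.0778).

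Some neighbours that rose differed widely in the size of the rise. On chromosome 10 at 17657254 to 17670159, a locus rose from 8.40 ± 0.906 to 122 ± 5.38 FPKM beside one that rose from 0.971 ± 0.275 to 3.01 ± 0.255 FPKM (n = 3 per group). On chromosome 2 at 8930778 to 8940622, a rise from 5.43 ± 0.357 to 71.7 ± 4.21 FPKM lay beside one from 1.87 ± 0.132 to 5.38 ± 1.22 FPKM. Pairs that rose were on the same strand in 14 of 32 cases (43.8%), against 46.7% of 22011 adjacent tested pairs (odds ratio 0.886, 0.408 to 1.89, Fisher's exact test, two-sided, p = 0.86). Among the 10 that overlap 1 was on the same strand, and among the 22 that do not overlap 13 were (59.1%), against 48.1% of 20938 such adjacent pairs (odds ratio 1.56, 0.616 to 4.13, p = 0.394, Fisher's exact test, two-sided). The pairs given by position were picked out after their values were seen.

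Far more loci rose at least 2-fold than fell. The lowest ratio of rises to falls over 3 scalings was 3.49, and without air-dried replicate 1 it was 3.97, which argues against scaling or that library as the whole cause. Among loci with no transcript spanning under 1000 bases the ratio was 8.20 (361 and 44), so the excess was not confined to loci of short span. Spans include introns, so short transcripts remain in that set and it cannot decide on fragment length. An early response to lifting, rinsing and drying that is mostly induction may be a biological explanation, but drying and handling were not separated by the design. The real grouping gave 1655 higher, 638 lower, 496 2-fold higher and 67 2-fold lower loci, and the highest of the other splits gave 10, 4, 10 and 4. In each case 1 of 10 splits was as large, the real one included, and 10 splits are too few for a share under 0.05.

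Rises were concentrated in loci of short genomic span. The odds ratio between spans over 1000 up to 2000 and over 4000 up to 8000 bases was 10.97 without air-dried replicate 1 (7.84 to 15.7), 10.99 within quintiles of mean expression (7.78 to 15.5, Mantel-Haenszel) and 27.1 among loci with 1 transcript (4.76 to 1078, from 151 and 1 loci), which argues against an altered fragment length in that library, expression level and the summing of transcripts as the whole cause. Slow completion of long transcripts within 10 min could give such a pattern for rises. Falls leaned the same way with an odds ratio of 4.29 (1.83 to 10.8), so delay would not account for the lean in both directions. For the rises alone this cannot decide, since falls may lean this way for a separate reason. Why loci over 1000 up to 2000 bases changed more often in both directions than those over 4000 up to 8000 bases stays open. At spans up to 300 bases 1.43% of loci rose at least 2-fold, against 1.51% over 2000 up to 4000 bases. These shares cannot show where the lean ends. In the shortest class air-dried replicate 1 exceeded the mean of air-dried replicates 2 and 3 by a median of 2.85 log2 units, a spread that hinders calls. The median log2 change there was 0.69, the largest of any span class.

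Neighbouring loci rose together. No shuffle of 10000 reached the observed number of adjacent pairs (permutation p = 0.0001, the smallest they can give), and for pairs more than 5000 bases apart the permutation p was 0.0006, which argues against chance order and against reads running on into the next locus as the whole cause. Reads shared between near-identical tandem copies could still contribute: the 14 same-strand pairs, 1 of them overlapping, differed by a median of 1.53 log2 units in air-dried FPKM, which excludes nothing, since sharing can be partial and sequences were not used here. Joint regulation of neighbours, or of duplicated genes with like promoters, may be a biological explanation, and the 2 cannot be told apart from shared reads without sequences.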
